A study of Mus musculus with 90 samples.

How the data were processed

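Gene expression was measured on Affymetrix mouse expression arrays in 90 samples of subcutaneous melanoma allograft tumour, with 1 array per sample. The labels give the genotype as an Hgf transgene together with the R24C knock-in of Cdk4, and the mouse strain as B6.cBrd. RNA was purified on columns, 800 ng were amplified, and the product was labelled with biotin. The arrays fall into 7 groups: PBS (7), control IgG (22), Responder (27), NonResponder (23), Relapse (6), GrowthDelay (2) and Stabilization (3). The labels do not state that each array comes from a separate mouse, so every p-value measures the spread between these samples.

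The deposited values are on the log2 scale and, per the submitters' processing notes, were normalized by the authors with RMA (robust multi-array average), with limma also named there. No version of either tool and no statement of which arrays were normalized together is given in the sources used here. The values ran from 2.19 to 14.8, and no pair of the 90 columns was identical. Array medians lay between 5.71 and 5.9, and the mean correlation of an array with the others between 0.901 and 0.984. Arrays give no read depth, so their number limits the precision.

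The deposited table holds 45101 probe sets. Control probe sets (64) were left out, 34945 probe sets carried 1 gene symbol in the annotation, 932 carried several and 9160 were not listed there. Each of the 18193 genes was represented by the probe set with the highest mean over all arrays, which involved a choice for 9010 genes. Probe sets that were not listed, or listed with several symbols, entered no gene result. No genome was at hand, so no positions are given.

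Title numbers fall into 4 separate ranges, called title series here. The larger title series (53 arrays) and the smaller one (25 arrays) both hold Responder, NonResponder and Relapse tumours. The remaining ranges hold 8 control IgG arrays alone and 4 PBS arrays alone, so their arrays add to the estimate of spread but not to a difference between groups. GrowthDelay tumours lie in the larger series only and Stabilization tumours in the smaller series only. Nothing in the labels says what the ranges stand for.

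All 90 arrays entered 1 linear model per gene (limma 3.58.1 in R 4.3.3, lmFit and eBayes) with the group and the title series as fixed terms. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided and over all 18193 genes, are called changed. Differences are given as log2 fold change with the standard error from limma; fold changes are powers of 2 of these. The difference between Responder and control IgG borrows the Responder minus NonResponder difference of the smaller series through the shared block. The direct difference within the larger series is therefore also given for the largest changes and, as a median, for the lists described. NonResponder against control IgG and the GrowthDelay comparisons borrow it as well, and direct medians are given there beside the list medians. Whether the Responder minus NonResponder difference depended on the title series was tested as an interaction in a model with a mean for each group and series.

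Lists of marker and pathway genes (27 lists, 366 genes, 331 of them measured) were fixed before the data were examined. So were the comparisons, their tests, the rule for naming genes and most of the alternatives. Tests of patterns seen in these data, given in the closing sections, were fixed before their own results were seen, not before the data. For each list the members past the threshold over all genes are counted, beside the count adjusted over the list alone. Whether a list moved against the other genes was tested with camera, with limma's preset correlation between genes and with a correlation estimated from the arrays. No list passed in any comparison with the estimated correlation. The fry test asks whether a list's genes move on balance in 1 direction and compares the list with no other gene. Within-series values are direct differences of group means inside a title series. Scores per array are the mean log2 value of a list's measured genes.

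The text names, for Responder against NonResponder, Responder against control IgG and NonResponder against control IgG, the 10 largest rises and 10 largest falls among called genes whose difference has the same sign in every title series that holds both groups. For the other comparisons it takes 5 and 5. To these come up to 4 members with the smallest p of each list described, and Cd274, Pdcd1, Hgf and Cdk4 throughout. Immunoglobulin and T cell receptor segments and unnamed transcripts stay in the counts and are skipped among the largest rises and falls. The antibody chain gene Ighm is therefore named only as a list member.

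The procedure was tested on simulated data with 200 changed genes of 18193. With the group sizes of Responder against NonResponder it recovered 82% of genes changed by 0.5 on the log2 scale and 98% of those changed by 1, with 8 false calls. With the sizes of Relapse against NonResponder it recovered 58% and 96%, with those of Stabilization against NonResponder 40% and 88%, with those of GrowthDelay against NonResponder 48% and 72%, and with those of control IgG against PBS 52% and 76%. Simulated genes varied independently of each other and no array was made to stand apart. Real genes move together (estimated correlation 0.735 in the cytotoxic list), so these rates and the few false calls may not carry over.

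Alternatives left out dim genes, those with a mean under 7.01, the median over all genes. Others dropped or reduced the series block, or used only the larger or only the smaller series. Quantile normalization or median centring was added, all probe sets of a gene were averaged, or the arrays were weighted. Further alternatives fitted only the groups compared, or let the variance prior follow intensity. Each Relapse, Stabilization and GrowthDelay array, and each PBS array of the larger series, was also left out in turn. After the data were seen, 5 arrays were set apart as doubtful: NonResponder replicate 14, Responder replicates 20 and 21 and Stabilization replicate 1 had a mean correlation with the other arrays under 0.95, and PBS replicate 5 had an actin control signal 6.09 higher on the log2 scale at the 3' end than at the 5' end. Alternatives without these arrays, and a gene-by-gene estimate of the array weights, were therefore chosen after the data were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.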

Results

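RNA of 90 melanoma allografts grown under the skin of mice was profiled after treatment with an antibody against PD-L1 (mouse IgG1 with the D265A change in its Fc part), with an isotype control antibody (control IgG) or with PBS. The labels give a dose of 10 mg/kg for both antibodies and 10 ml/kg for PBS. They define the groups treated with the antibody against PD-L1 by tumour growth. Responder tumours (27) had shrunk by at least 5% and were taken after 2 to 12 doses, and NonResponder tumours (23) grew on and were taken at matching times. Relapse tumours (6) had shrunk below measurement and regrown, after 4 to 10 doses. GrowthDelay tumours (2) appeared only after treatment, and Stabilization tumours (3), a subset of the Responder design, kept their volume between consecutive measurements. Control IgG (22) and PBS (7) tumours served for comparison. The array medians of the 90 samples differed by little, from 5.71 to 5.9 on the log2 scale.

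**Figure D1:**
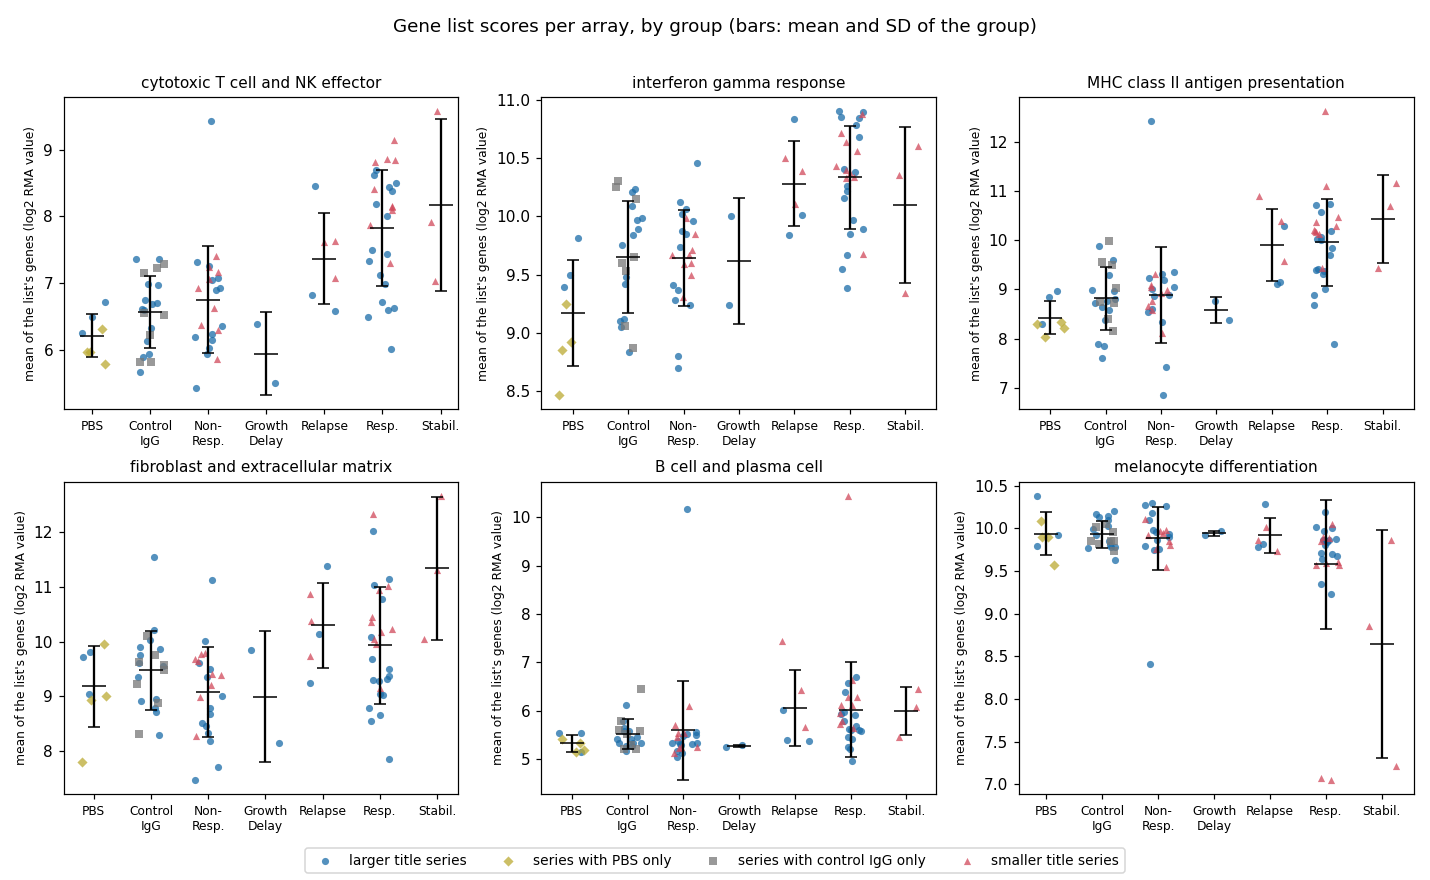
Scores of 6 gene lists per array (mean log2 RMA value of the list's genes, y axis) by group (x axis). Each point is 1 array, coloured by title series, and bars give the group mean and SD. The cytotoxic score had a mean of 7.83 in 27 Responder tumours and 6.75 in 23 NonResponder tumours, and 6.57 in 22 control IgG tumours.

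Responder against NonResponder asks how tumours that regressed under the antibody differed from tumours that grew under the same antibody. Genes of T cells, of the interferon gamma response and of antigen presentation were higher in the Responder tumours, with 11 of 13 T cell receptor, 13 of 14 interferon gamma, 14 of 14 class I and 7 of 9 class II genes. None of their lists passed camera with an estimated correlation (adjusted p = 0.129 to 0.184). The fry test, which compares a list with no other gene, passed for these lists. Its adjusted p was 1.74e-05 for interferon gamma, 2.79e-05 for class I, 7.04e-05 for class II and 0.000286 for T cell receptor genes. Ubd, a ubiquitin-like modifier induced by interferon gamma, was 4.63-fold higher (log2 2.21 ± 0.40, SE; limma adjusted p = 0.000103; 27 against 23 arrays), with a mean of 9.67 (SD 1.51) against 7.49 (SD 1.66). Cd3g, a chain of the T cell receptor complex, was 3.99-fold higher (log2 2.00 ± 0.34, adjusted p = 5.17e-05). Pmel, the fibril protein of pigment granules, fell by 0.93 on the log2 scale (SE 0.30, adjusted p = 0.0114), from a mean of 11.7 (SD 0.87) to 10.8 (SD 1.48). Cd274, which encodes the antibody's target PD-L1, rose 1.67-fold (log2 0.74 ± 0.12, adjusted p = 5.17e-05), and Pdcd1, which encodes its receptor PD-1, rose 2.28-fold (log2 1.19 ± 0.21, adjusted p = 0.000103).

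Of 18193 genes, 8552 (47%) changed, 3138 higher and 5414 lower, and 183 changed by more than 2-fold, 180 of them higher. The larger rises of the named genes took in the interferon-induced guanylate-binding proteins Gbp8 (1.93 ± 0.31) and Gbp2b (1.91 ± 0.34), the myeloid surface receptor Slamf8 (1.84 ± 0.31) and the joining chain of antibodies Jchain (1.82 ± 0.45), all as log2. They were followed by the chemokine receptor Cxcr6 (1.69 ± 0.31), the chemokine Ccl5 (1.61 ± 0.27), the class II invariant chain Cd74 (1.58 ± 0.30) and the granule protein Nkg7 (1.56 ± 0.28). Genes with the larger falls were Gsta4, a glutathione transferase (-1.25 ± 0.28), the anion exchanger Slc26a7 (-1.16 ± 0.27), the G protein subunit Gng8 (-1.03 ± 0.21) and the fatty acid-binding protein Fabp3 (-0.89 ± 0.26). Next came the tryptophan hydroxylase Tph2 (-0.88 ± 0.28), Azgp1 (-0.88 ± 0.23), the prostaglandin D synthase Ptgds (-0.85 ± 0.24), Rec114 (-0.83 ± 0.29) and the isoprenoid enzyme Idi1 (-0.81 ± 0.24). Transcripts of the transgene's gene did not pass the test (Hgf -0.26 ± 0.27, adjusted p = 0.414; 0.24 within the larger and -1.08 within the smaller series). Cdk4, the knock-in gene, fell by 0.34 (SE 0.09, adjusted p = 0.0037). The excess of falling genes depended on dim genes: with these left out, 4397 genes changed and 54.4% were higher, against 36.7% of 8552. Median centring moved it the other way, to 11185 changed genes with 18.4% higher.

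Both title series held both groups, and the differences within them had a correlation of 0.731 over all genes. Cd3g differed by 1.54 within the larger series and by 2.73 within the smaller one, and Ubd by 1.87 and 2.77. Cd274 differed by 0.54 and 1.06, Gsta4 by -0.66 and -2.19 and Pmel by -0.58 and -1.49. With a mean for each group and series, 478 genes changed in the larger series and 6678 in the smaller one, with 209 in both. Fitted alone the series gave 550 and 3467 genes, and without the 5 doubtful arrays, set apart after the data were seen, the order turned round to 4396 and 1849. Of the list members described below, the larger series fitted alone called 6 of 14 interferon gamma, 2 of 16 cytotoxic, 2 of 13 T cell receptor and 1 of 14 class I genes. It called 1 gene each of the inhibitory receptor, B cell, dendritic cell, dedifferentiation, hypoxia and complement lists. In limma it called 0 genes of all other lists, among them class II, macrophage, PD-1 axis, matrix, melanocyte, proliferation, oxidative phosphorylation, TGF-beta and endothelial genes. The interaction itself called 0 genes in limma (2418 at an unadjusted p under 0.05; smallest adjusted p = 0.0586).

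Cytotoxic T cell and natural killer genes rose in 14 of 16 measured members (14 adjusted over the list alone), with a median of 1.27 and medians of 0.90 and 1.84 within the larger and the smaller series. Ifng (1.52 ± 0.25), the transcription factor Tbx21 (1.52 ± 0.26) and the protease inhibitor Cst7 (1.37 ± 0.24) were among them. The list passed camera with the preset correlation and lost the call with an estimated one (adjusted p = 0.129 with an estimated correlation). T cell receptor and costimulation genes rose in 11 of 13 members and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation). Cd5 rose by 1.32, Cd2 by 1.17 and Cd27 by 1.12. Inhibitory receptor and regulatory T cell genes rose in 9 of 13 (9 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation), including Ikzf2 (0.50), Havcr2 (1.04) and Ctla4 (0.68). In the PD-1 axis list 3 of 4 members rose (3 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation). Pdcd1lg2 rose by 0.85 ± 0.17, and Cd80 stood at -0.01 ± 0.06 (adjusted p = 0.913).

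Interferon gamma response genes rose in 13 of 14 members (13 higher and 1 lower adjusted over the list alone), by a median of 0.68 and by 0.62 and 0.86 within the series. The call of the list was lost, at an adjusted p of 0.129, with an estimated correlation. The macrophage and dendritic cell regulator Irf8 rose by 1.40, the T cell attractant Cxcl9 by 1.5, the signalling inhibitor Socs1 by 0.72 and the GTPase Igtp by 0.81. All 14 class I antigen presentation genes rose (14 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation). Among them were the class I regulator Nlrc5 (0.59), the peptide transporters Tap1 (0.74) and Tap2 (0.85) and the loading factor Tapbp (0.73). Class II genes rose in 7 of 9 (7 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation). H2-DMa rose by 1.39, H2-Ab1 by 1.46 and H2-Eb1 by 1.51. Of the type I interferon genes 4 of 15 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.605 with an estimated correlation). Oasl2 rose by 0.51, Mx1 by 0.45 and Irf7 by 0.36, and Mx2 fell by 0.22. Without the 5 doubtful arrays 10 of the 15 rose and 1 fell.

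**Figure D2:**
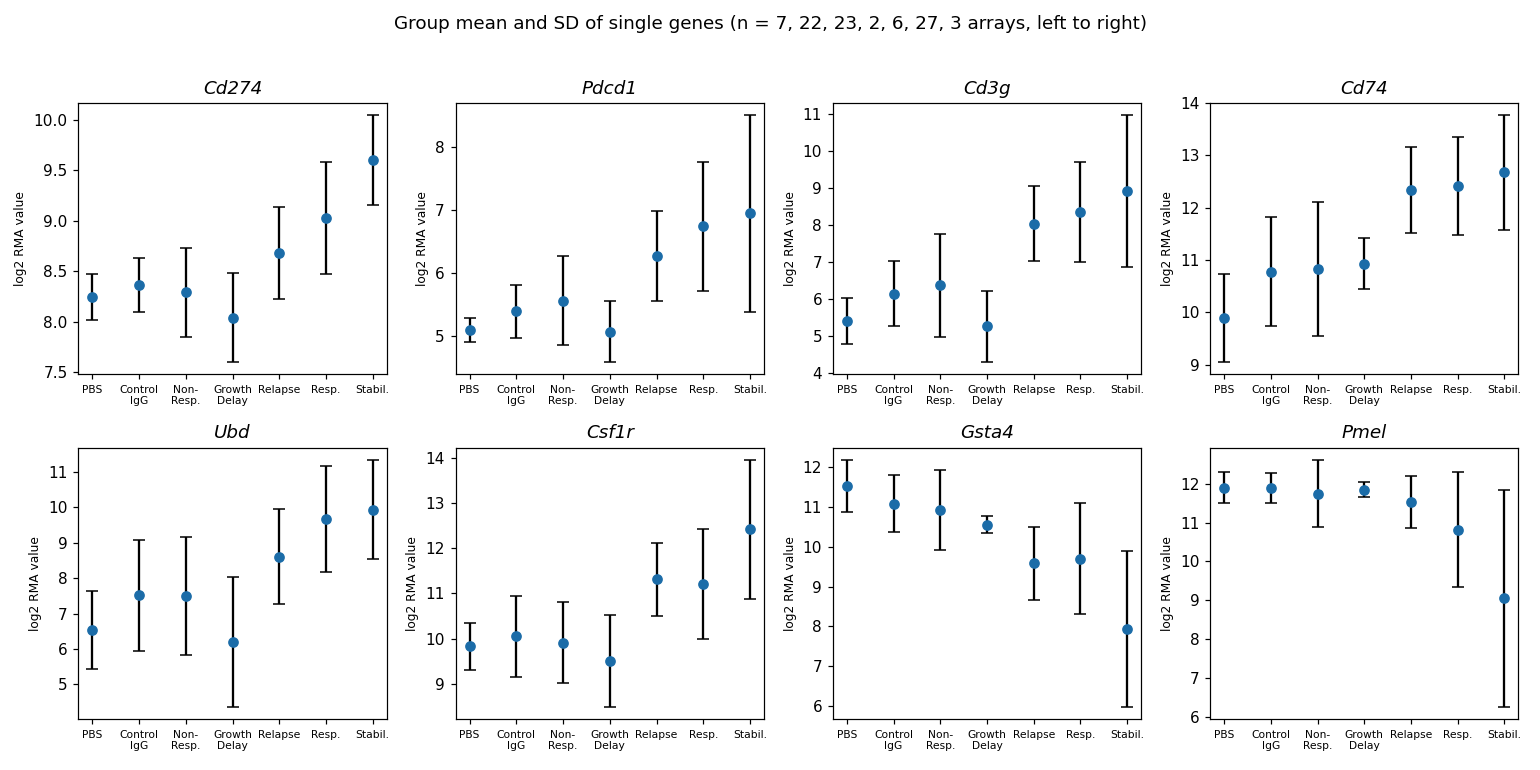
Group means of single genes (log2 RMA value, y axis) in the 7 groups (x axis), with bars for the SD. Cd274 had means of 8.37 in control IgG, 9.03 in Responder, 8.29 in NonResponder and 8.68 in Relapse tumours, and Cd3g means of 6.14, 8.35, 6.37 and 8.03.

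Macrophage genes rose in 11 of 15 members (11 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation). The growth factor receptor Csf1r rose by 1.32 ± 0.27, the engulfment receptor Mertk by 0.75 ± 0.15 and the complement genes C1qc and C1qb by 0.89 and 0.83. Complement and coagulation genes rose in 7 of 10 (8 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation). These included the complement inhibitor Serping1 (1.47 ± 0.25), the proteases C1s1 (1.34) and C1ra (1.15) and Cfb (0.85). Neutrophil genes rose in 3 of 12 (3 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation). Csf3r rose by 0.60, Il1b by 0.51 and Mmp8 by 0.29, while S100a9 stood at 0.75 ± 0.37 (adjusted p = 0.0806). Dendritic cell genes rose in 3 of 12 (3 adjusted over the list alone), Ccr7 by 0.79, Clec10a by 0.95 and Fscn1 by 0.27. The median of the list was 0.08 and turned to -0.003 with median centring.

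B cell and plasma cell genes rose in 3 of 14 members (2 adjusted over the list alone, adjusted p = 0.632 with an estimated correlation). Besides Jchain these were Ighm, by 1.79 ± 0.38, and Cd22, by 0.59 ± 0.26. The median of this list was -0.12 within the larger series and 0.89 within the smaller one. NonResponder replicate 14 and Responder replicate 20 held by far the highest B cell scores of their groups. These were 10.2 against a mean of 5.38 in the other 22 NonResponder tumours and 10.4 against 5.85 in the other 26 Responder tumours. Lymph node stroma genes were also high in these samples, with scores of 8.58 and 8.83 against means of 5.14 (SD 0.15) and 5.39 (SD 0.28). Without the 5 doubtful arrays 7 B cell genes rose and 1 fell. Of the 5 lymph node stroma genes measured, Ltb, a lymphotoxin chain made by lymphocytes, rose by 1.43 and the vessel addressin Madcam1 fell by 0.30 (1 and 1 adjusted over the list alone). The median of the list (-0.09) and its mean (0.24) differed in sign.

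**Figure D3:**
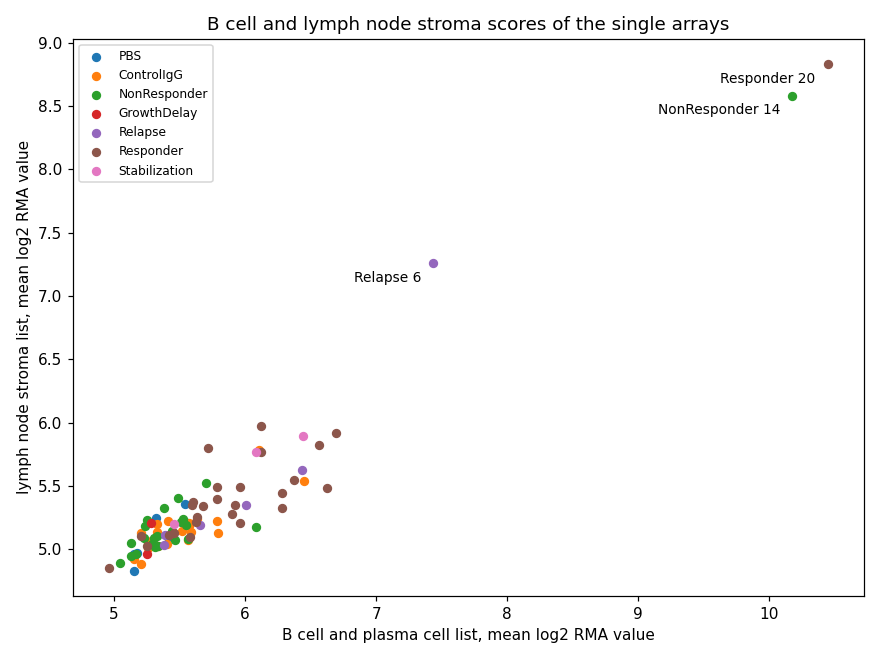
Score of the lymph node stroma list (y axis) against the score of the B cell and plasma cell list (x axis), both as mean log2 RMA value, with 1 point per array coloured by group. NonResponder replicate 14 (10.2 and 8.58) and Responder replicate 20 (10.4 and 8.83) lie apart from the others.

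Melanocyte differentiation genes fell in 5 of 15 members, with no rise past the threshold in limma (5 adjusted over the list alone, camera adjusted p = 0.087 with the preset correlation). The median was -0.26 over both series, and -0.09 and -0.61 within them. Besides Pmel these included the channel Trpm1 (-0.33), the pigment granule GTPase Rab27a (-0.42) and the receptor Gpr143 (-0.69). Genes of dedifferentiated melanoma rose in 6 of 14 and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation). Among them were the receptor kinase Axl (0.72), Zeb1 (0.67), Jun (0.67) and Twist1 (0.50). Proliferation genes fell in 6 of 18 (5 adjusted over the list alone, camera adjusted p = 0.539 with the preset correlation). Pcna fell by 0.25, Birc5 by 0.28, Ccnb2 by 0.34 and Cdk1 by 0.35, and the list's median was 0.01 within the larger series and -0.30 within the smaller one. Over all genes 5414 of 18193 were called lower, a similar share. The counts of the melanocyte and proliferation lists therefore do not set them apart from other genes. Oxidative phosphorylation genes fell in 8 of 16 (8 adjusted over the list alone, adjusted p = 0.487 with an estimated correlation), such as Sdhb (-0.24), Uqcrfs1 (-0.21), Atp5j (-0.19) and Cox4i1 (-0.15). Hypoxia and glycolysis genes rose in 4 of 14 (4 adjusted over the list alone, adjusted p = 0.454 with an estimated correlation), and in 7 without the doubtful arrays. Hk2 rose by 0.46, Slc2a1 by 0.39, Ndrg1 by 0.37 and Aldoa by 0.26.

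Fibroblast and extracellular matrix genes rose in 16 of 18 members (16 adjusted over the list alone, adjusted p = 0.248 with an estimated correlation). The median was 0.90, and 0.72 and 1.11 within the series. Collagen genes led the list: Col1a1 (1.44 ± 0.38), Col6a2 (1.27 ± 0.33), Col6a1 (1.26 ± 0.32) and Col5a1 (0.95 ± 0.23). TGF-beta response genes rose in 6 of 11 (8 adjusted over the list alone, adjusted p = 0.256 with an estimated correlation), including Tgfbi (1.03), Ltbp2 (0.97), Tgfb1 (0.85) and Ski (0.49). Endothelial genes rose in 5 of 12 (5 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation), including Pecam1 (0.55), Cdh5 (0.53), Tie1 (0.50) and Eng (0.29).

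Lists for neighbouring tissues held few members past the threshold. Mast cell and eosinophil genes rose in 2 of 10 (0 adjusted over the list alone), Cma1 by 0.45 and Cpa3 by 0.38, though within the larger series these differed by 0.02 and -0.08. The list's median (-0.07) and mean (0.06) differed in sign. Keratinocyte genes fell in 3 of 12, no larger a share than the 5414 of 18193 over all genes, and rose in 1 (3 and 1 adjusted over the list alone). Krt1 stood at -0.18, Krt15 at -0.16, Lor at -0.13 and Perp at 0.23, and the list's median of -0.05 became 0.03 with quantile normalization. No skeletal muscle gene of 14 passed in limma (Ckm -0.54 ± 0.52, adjusted p = 0.39). That list's median was -0.31 although camera put it on the upper side. It was -0.96 within the larger series and 0.70 within the smaller one. Responder replicate 21 had the highest muscle score of its group, 13.7, against a group mean of 6.80 (SD 2.46). Adipocyte genes rose in 1 of 8 (1 adjusted over the list alone, adjusted p = 0.487 with an estimated correlation). The lipase Lipe rose by 0.67 ± 0.21, and Adipoq stood at 0.94 ± 0.61 (adjusted p = 0.185, -0.50 and 3.27 within the series). Among erythroid genes 1 of 5 fell (1 adjusted over the list alone), the globin gene Hba-a2 by 0.67 ± 0.24. Adipocyte scores were high in the samples with high lymph node scores, 10.97 in Responder replicate 20 and 9.22 in NonResponder replicate 14.

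Responder against control IgG compares regressing tumours with tumours that received an antibody without the target. T cell, interferon gamma and antigen presentation genes were higher in the regressing tumours, with 13 of 16 cytotoxic, 13 of 14 interferon gamma and 12 of 14 class I genes. None of their lists passed camera with an estimated correlation (adjusted p = 0.362 to 0.405). With fry, which compares a list with no other gene, the adjusted p was 0.000839 for cytotoxic and 0.000433 for interferon gamma and class I genes. Cd3g was higher by 2.03 ± 0.41 on the log2 scale (adjusted p = 0.000464), Ccl5 by 1.81 ± 0.33 (adjusted p = 0.00014), Cd274 by 0.57 ± 0.15 (adjusted p = 0.00411) and Pdcd1 by 1.18 ± 0.26 (adjusted p = 0.00111). Serpinb2, an inhibitor of plasminogen activators, had the largest fall, by 2.40 (SE 0.59, adjusted p = 0.00259). Of 18193 genes 6791 (37.3%) changed, 2641 higher and 4150 lower, and 108 changed by more than 2-fold, 105 of them higher. Control IgG and Responder arrays shared only the larger series (14 and 17 arrays), where the direct differences were 1.83 for Cd3g, 1.65 for Ccl5, 0.48 for Cd274, 1.001 for Pdcd1 and -2.41 for Serpinb2.

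Further rises were Gbp2b (1.99 ± 0.41), Ubd (1.96 ± 0.48), Gbp8 (1.89 ± 0.38), Cxcr6 (1.67 ± 0.38), Cd74 (1.63 ± 0.36), the CD8 chain Cd8b1 (1.61 ± 0.34), Nkg7 (1.58 ± 0.34) and Ipcef1 (1.58 ± 0.35). Further falls were Gsta4 (-1.25 ± 0.34), Slc26a7 (-1.18 ± 0.33), Tph2 (-0.98 ± 0.34), Avpi1 (-0.95 ± 0.22), Fabp3 (-0.94 ± 0.32), the potassium channel subunit Kcne3 (-0.94 ± 0.29), Gng8 (-0.93 ± 0.26), Pmel (-0.93 ± 0.37) and the cytokine gene Il6 (-0.92 ± 0.32). Cdk4 fell by 0.31 (SE 0.11, adjusted p = 0.0263), and Hgf stood at -0.17 ± 0.33 (adjusted p = 0.693). Directly within the larger series Gbp2b differed by 1.76, Ubd by 1.78, Gbp8 by 1.75, Cxcr6 by 1.52, Cd74 by 1.48, Cd8b1 by 1.41, Nkg7 by 1.43 and Ipcef1 by 1.35. The direct values were -0.995 for Gsta4, -0.97 for Slc26a7, -0.845 for Tph2, -0.92 for Avpi1, -0.88 for Fabp3, -0.81 for Kcne3, -0.82 for Gng8, -0.77 for Pmel and -0.94 for Il6, with Cdk4 at -0.26 and Hgf at 0.09.

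Cytotoxic genes rose in 13 of 16 members (13 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation). Their median was 1.26, and 1.11 within the larger series, with Ifng at 1.55 and Tbx21 at 1.53. T cell receptor genes rose in 11 of 13 and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.405 with an estimated correlation), the falling one being Zap70 (-0.22). Inhibitory receptor genes rose in 9 of 13 and fell in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.405 with an estimated correlation), with Havcr2 at 1.07 and Lag3 at 0.84. Interferon gamma genes rose in 13 of 14 (13 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation), with Irf8 at 1.20 and Gbp3 at 0.58. Class I genes rose in 12 of 14 (13 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation) and class II genes in 6 of 9 (7 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation). Tap2 rose by 0.91 and H2-Eb1 by 1.53. Macrophage genes rose in 7 of 15 (7 adjusted over the list alone, adjusted p = 0.732 with an estimated correlation), among them Csf1r (1.06) and C1qa (0.76). In the matrix list 1 of 18 rose and 1 fell (0 adjusted over the list alone; median 0.17). Pdgfrb stood at 0.81 and Tagln at -0.70, while Col1a1 stood at 0.82 ± 0.46 (adjusted p = 0.14). Melanocyte genes fell in 5 of 15 (1 adjusted over the list alone; median -0.15), and erythroid genes in 2 of 5 (3 adjusted over the list alone), Slc4a1 by 0.45 and Alas2 by 0.90. Oxidative phosphorylation genes fell in 7 of 16 (7 adjusted over the list alone; median -0.10), among them Cox6c (-0.21) and Ndufa4 (-0.39). Direct medians within the larger series were 0.85 for the T cell receptor list, 0.28 for inhibitory receptors, 0.62 for interferon gamma, 0.315 for class I, 1.08 for class II and 0.26 for macrophages. They were 0.05 for the matrix list, -0.10 for melanocyte genes, -0.565 for erythroid genes and -0.10 for oxidative phosphorylation. Quantile normalization lowered the number of changed genes to 4132. Leaving out dim genes lowered it to 3448, of which 64.2% were higher, against 38.9%. With median centring 8234 genes changed, 2012 higher and 6222 lower (24.4% higher).

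NonResponder against control IgG asks whether tumours that grew under the antibody differed from tumours under control antibody. In limma 0 genes changed (838 at an unadjusted p under 0.05; smallest adjusted p = 0.537; 23 against 22 arrays, 14 and 14 in the shared larger series). Cd274 stood at -0.17 ± 0.15 and Pdcd1 at -0.02 ± 0.27 (both adjusted p = 1), and Hgf and Cdk4 at 0.09 ± 0.34 and 0.03 ± 0.12. The cytotoxic list had a median of 0.02 and the interferon gamma list one of -0.03, the latter turning to 0.001 with median centring. Directly within the larger series these medians were 0.18 and 0.02. For T cell receptor genes the direct median was 0.25 (0.035 in the joint fit), and for class II genes 0.25 (0.024 in the joint fit). Matrix genes had a median of -0.66, passed camera with the preset correlation (adjusted p = 1.24e-12) and lost the call with an estimated one (adjusted p = 0.263 with an estimated correlation). Over the list alone 4 of the 18 were lower: Dcn stood at -1.36 ± 0.48, Lox at -1.18, Col3a1 at -1.08 and Tagln at -0.88 ± 0.28, none past the threshold over all genes. Of 12 neutrophil genes 3 were lower adjusted over the list alone (adjusted p = 0.246 with an estimated correlation), with S100a8 at -1.59, S100a9 at -1.56 ± 0.46 and Il1b at -0.59. The hypoxia list had a median of -0.28 (adjusted p = 0.35 with an estimated correlation) and the macrophage list one of -0.27 (adjusted p = 0.468 with an estimated correlation), with Arg1 at -1.23. Direct medians within the larger series were -0.60 for matrix, -0.15 for neutrophil, -0.305 for hypoxia and -0.21 for macrophage genes.

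Control IgG against PBS measures the background of antibody treatment without the target. A single gene passed in limma (240 at an unadjusted p under 0.05): Hsd3b1, an enzyme of steroid synthesis, was lower by 1.42 on the log2 scale in control IgG tumours (-1.42 ± 0.26, adjusted p = 0.00841; 22 against 7 arrays, 14 and 3 in the shared series). Its mean was 4.15 (SD 0.15) against 4.78 (SD 1.60), and without PBS replicate 1, which decided the call, 0 genes passed. Hypoxia genes had a median of 0.41 (adjusted p = 0.567 with an estimated correlation), with Car9 at 1.45 ± 0.63, and muscle genes one of -1.77 (adjusted p = 0.926 with an estimated correlation), with Acta1 at -2.53 ± 1.79. None of the genes of these lists passed. Cd274 stood at 0.08 ± 0.28 and Pdcd1 at 0.14 ± 0.48. Leaving out PBS replicate 2 or PBS replicate 3 gave 2 genes each.

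**Figure D4:**
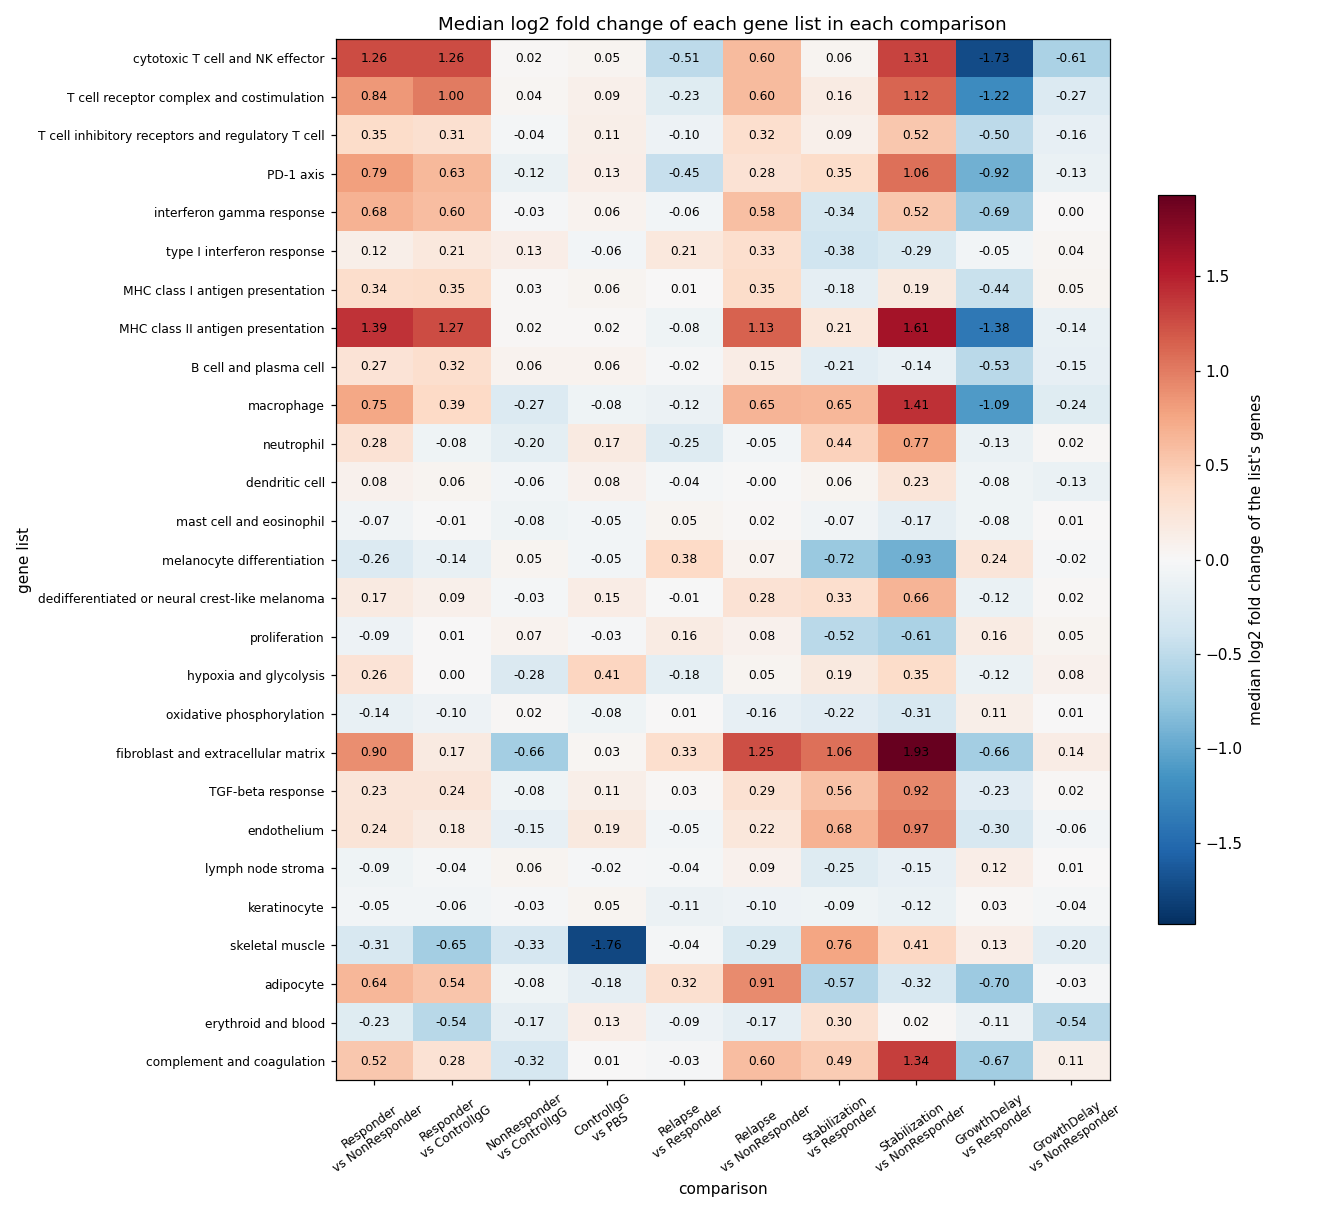
Median log2 fold change of each gene list (y axis) in each comparison (x axis), as colour and number. For the cytotoxic list the median was 1.27 in Responder against NonResponder, 0.02 in NonResponder against control IgG and 0.61 in Relapse against NonResponder.

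Relapse against NonResponder sets regrown tumours beside tumours that never shrank. Part of the matrix, antigen presentation and interferon gamma genes were higher in the Relapse tumours. None of these lists passed with an estimated correlation, and the larger series fitted alone called 0 of their genes in limma. Col1a1 was higher by 1.93 ± 0.61 on the log2 scale (adjusted p = 0.027; 6 against 23 arrays), by 2.11 within the larger and 1.75 within the smaller series. Jchain was higher by 1.99 ± 0.73 (adjusted p = 0.0454, with 1.04 and 3.14 within the series) and Cd3g by 1.59 ± 0.54 (adjusted p = 0.0351). Relapse replicate 6, in the smaller series, had a lymph node stroma score of 7.26, against 5.04 to 5.63 in the other Relapse tumours. Gsta4 fell by 1.22 (SE 0.45, adjusted p = 0.0449; -0.82 and -1.81 within the series). Cd274 (0.38 ± 0.20, adjusted p = 0.133) and Pdcd1 (0.65 ± 0.35, adjusted p = 0.14) did not pass, nor did Hgf (0.35 ± 0.43) and Cdk4 (-0.18 ± 0.15). In all, 3697 genes (20.3%) changed, 1533 higher and 2164 lower, and 92 by more than 2-fold, 87 of them higher. The balance depended on the processing. Of 1559 genes called with dim genes left out 79.4% were higher, and of 7349 with median centring 10.8%, against 41.5%.

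Itih5 (1.88 ± 0.59), the macrophage protein Cd5l (1.71 ± 0.61) and Col6a2 (1.69 ± 0.53) also rose, and Kcne3 (-1.19 ± 0.39), Rragd (-1.05 ± 0.32), Ptgds (-1.05 ± 0.38) and Gng8 (-1.05 ± 0.35) fell. Matrix genes rose in 9 of 18 (16 adjusted over the list alone; median 1.247, and 1.53 and 0.97 within the series, adjusted p = 0.666 with an estimated correlation). Interferon gamma genes rose in 8 of 14 (11 adjusted over the list alone, adjusted p = 0.666 with an estimated correlation), including Gbp3 (0.57), Igtp (0.79) and Irf8 (1.17). Class I genes rose in 6 of 14 (11 adjusted over the list alone, adjusted p = 0.666 with an estimated correlation), with Nlrc5 at 0.74 and Tap2 at 0.94. Class II genes rose in 5 of 9 (6 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation), with Cd74 at 1.51 and H2-Aa at 1.35. Complement genes rose in 4 of 10 (6 adjusted over the list alone, adjusted p = 0.666 with an estimated correlation) and macrophage genes in 4 of 15 (6 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation), with Serping1 at 1.41 and Csf1r at 1.32. Of 16 cytotoxic genes 2 rose, Cd8b1 by 1.24 ± 0.46 and Ccl5 by 1.15 ± 0.43 (0 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). Of the dedifferentiation genes 2 of 14 rose, Axl by 0.91 and Zeb1 by 0.81 (1 adjusted over the list alone). Oxidative phosphorylation genes fell in 4 of 16 (5 adjusted over the list alone), among them Atp5j (-0.27) and Cox6c (-0.21). With the doubtful arrays left out, 16 matrix, 11 interferon gamma, 11 class I, 9 class II, 7 complement, 6 macrophage, 6 cytotoxic and 5 dedifferentiation genes rose, and 8 oxidative phosphorylation genes fell. Taken alone, the larger series gave 0 genes in limma and the smaller one 542. Leaving out single tumours gave 557 genes without Relapse replicate 6, 785 without replicate 4, 1139 without replicate 5, 1359 without replicate 1 and 5626 without NonResponder replicate 14.

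Relapse against Responder asks whether tumours that had regrown differed from tumours caught in regression. In limma 0 genes changed (803 at an unadjusted p under 0.05; smallest adjusted p = 0.307; 6 against 27 arrays). Cytotoxic genes had a median of -0.51 and passed camera with the preset correlation (adjusted p = 1.87e-05) but not with an estimated one (adjusted p = 0.593 with an estimated correlation). Their median was -0.22 within the larger and -0.88 within the smaller series. Gzmb stood at -1.004, Gzma at -0.85 and Ifng at -0.85 ± 0.41. Melanocyte genes had a median of 0.38 (adjusted p = 0.593 with an estimated correlation; 0.11 and 0.56 within the series), with Slc45a2 at 0.76 and Sox10 at 0.58. The smaller series holds Responder replicate 20, with a melanocyte score of 7.05 against a mean of 9.68 in the other Responder tumours. Cd274 stood at -0.36 ± 0.20 and Pdcd1 at -0.54 ± 0.34, both with an adjusted p of 0.909.

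Stabilization against NonResponder sets tumours of steady volume beside growing tumours, and rests on 3 tumours of the smaller series, of which replicate 1 stood apart. Some macrophage, matrix and neutrophil genes were higher and some pigment and cell cycle genes lower. None of these lists passed with an estimated correlation, and in limma 0 or 1 gene of each changed without the doubtful arrays. The macrophage elastase Mmp12 was higher by 3.53 ± 0.77 on the log2 scale (adjusted p = 0.00257; 3 against 23 arrays), the proton pump subunit Atp6v0d2 by 3.15 ± 0.60 (adjusted p = 0.000967), S100a9 by 3.07 ± 0.82 (adjusted p = 0.00783), Serpinb2 by 3.01 ± 1.09 (adjusted p = 0.0372) and S100a8 by 3.01 ± 0.87 (adjusted p = 0.0118). Pmel fell by 2.55 (SE 0.68, adjusted p = 0.00779), and Mlana (-2.28 ± 0.65), Enho (-2.35 ± 0.48), Gsta4 (-2.33 ± 0.62) and Cth (-2.21 ± 0.49) fell as well. Cd274 rose by 1.26 ± 0.28 (adjusted p = 0.00257), Pdcd1 stood at 1.10 ± 0.48 (adjusted p = 0.0826) and Cdk4 fell by 0.73 (SE 0.21, adjusted p = 0.0112). Of 4074 changed genes (22.4%) 1912 were higher and 2162 lower, and 1125 changed by more than 2-fold, 827 of them higher. With median centring 31.6% of 5248 genes were higher, and in the smaller series fitted alone 60.2% of 2480, against 46.9%. Without Stabilization replicate 1, whose fibroblast and extracellular matrix score of 12.7 was the highest of the 3, 2 genes passed, and 872 without replicate 2 and 6666 without replicate 3.

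Macrophage genes rose in 11 of 15 (12 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), and in 1 without the doubtful arrays. Arg1 rose by 2.99, Cd68 by 1.98 and Cd14 by 1.94. Matrix genes rose in 15 of 18 (18 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), with Col5a1 at 2.11 and Thbs2 at 1.89, and in 0 of 18 in limma without these arrays. Neutrophil genes rose in 6 of 12 (7 adjusted over the list alone, adjusted p = 0.173 with an estimated correlation) and TGF-beta genes in 8 of 11 (10 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation). The activin gene Inhba of the latter list rose by 2.31 ± 0.35. Without the doubtful arrays these counts were 0 and 1. Proliferation genes fell in 12 of 18 (13 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation). Oxidative phosphorylation genes fell in 7 of 16 (12 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation) and melanocyte genes in 6 of 15 (12 adjusted over the list alone, adjusted p = 0.311 with an estimated correlation). Rrm2 fell by 0.79 and Uqcrfs1 by 0.65. Without the doubtful arrays 0 genes of each list changed in limma. T cell receptor genes rose in 5 of 13 (8 adjusted over the list alone, adjusted p = 0.311 with an estimated correlation), with Cd3g at 2.15 ± 0.75, and 4 changed without those arrays. Type I interferon genes fell in 2 of 15, Usp18 by 1.06 and Mx2 by 0.61 (2 adjusted over the list alone), and 0 changed in limma without those arrays.

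Stabilization against Responder compares steady with shrinking tumours. In all, 58 genes changed, 41 higher and 17 lower (3 against 27 arrays, 3 and 10 in the shared series). In limma 0 genes passed in the smaller series fitted alone, the only series the groups share, or with only the groups compared. Inhba was higher by 2.17 ± 0.35 (adjusted p = 0.000149), the surface glycoprotein gene Tpbg by 1.90 ± 0.46 (adjusted p = 0.0403), the endotoxin co-receptor Cd14 by 1.70 ± 0.41 (adjusted p = 0.0383), the growth factor Ereg by 1.58 ± 0.33 (adjusted p = 0.0113) and Tcfl5 by 1.5 ± 0.31. Tlcd4 fell by 2.08 (SE 0.34, adjusted p = 0.000149), and Gpm6a (-1.61 ± 0.38), St3gal6 (-1.48 ± 0.37), Art3 (-1.44 ± 0.35) and Klf15 (-1.31 ± 0.29) fell as well. Besides Inhba of the TGF-beta list and Cd14 of the macrophage list, the list members that rose were Wnt5a (1.16 ± 0.22; dedifferentiation list), Cd80 (0.65 ± 0.13; PD-1 axis), Mmp8 (1.04; neutrophil list) and Plau (0.89; complement and coagulation list), each the 1 member of its list past the threshold. Cd274 stood at 0.52 ± 0.27 (adjusted p = 0.41), Pdcd1 at -0.09 ± 0.48, Hgf at -0.79 ± 0.60 and Cdk4 at -0.39 ± 0.21. The count fell to 1 without Stabilization replicate 1 and was 72 without replicate 2, 2727 without replicate 3, 178 without Responder replicate 20 and 825 without Responder replicate 21.

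GrowthDelay against Responder compares 2 tumours that appeared late with 27 that shrank. Differences of T cell genes were large and negative but did not pass the test: the cytotoxic list had a median of -1.73 (-1.57 within the larger series), with Gzmb at -2.62, Nkg7 at -2.48 ± 0.73 (adjusted p = 0.147), Ccl5 at -2.26 and Prf1 at -1.61. None of its 16 members passed over all genes in limma and 15 were lower adjusted over the list alone, and the camera call with the preset correlation (adjusted p = 6.86e-19) was lost (adjusted p = 0.145 with an estimated correlation). Of 13 T cell receptor genes 7 were lower and 1 higher adjusted over the list alone (adjusted p = 0.236 with an estimated correlation). Cd274 stood at -0.95 ± 0.32 (adjusted p = 0.24) and Pdcd1 at -1.5 ± 0.56 (adjusted p = 0.315). The 29 genes that passed were all higher, with no change over 2-fold in limma. The named ones, Fam110b (0.62 ± 0.13), Umodl1 (0.61 ± 0.14), Slc15a5 (0.59 ± 0.12), S100g (0.59 ± 0.14) and Izumo1 (0.58 ± 0.12), are dim genes. With dim genes left out 0 passed. The count was 116 without GrowthDelay replicate 1 and 0 without replicate 2, where the lone sample is assumed to vary like the other groups.

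GrowthDelay against NonResponder gave 0 genes in limma (567 at an unadjusted p under 0.05; smallest adjusted p = 0.315; 2 against 23 arrays). Cd274 stood at -0.21 ± 0.32 and Pdcd1 at -0.31 ± 0.56. The cytotoxic list had a median of -0.61 (-0.76 within the larger series). Its camera call with the preset correlation (adjusted p = 0.000788) was lost (adjusted p = 0.995 with an estimated correlation). Without GrowthDelay replicate 1, 28 genes passed.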

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

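The alternatives without the doubtful arrays were chosen after the data were seen; the other tests of this part were fixed before their results were seen.

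The difference between Responder and NonResponder tumours was larger in the smaller title series. Over the genes called in the joint fit, the smaller series rose on the larger with a slope of 1.82 through 0. Exchanging the series among arrays within each group gave as large a slope in 2 of 100 draws, the real one included (highest other 1.92, median 0.998). The genes were called in these same arrays with their real series, so the count does not settle whether the division arose by chance. Without the doubtful arrays the slope was 1.16, and the ratio of the median sizes fell to 1.13 from 1.73, so a few arrays, NonResponder replicate 14 in the larger series and Responder replicates 20 and 21 in the smaller one, are a candidate explanation. Leaving out 1 array at a time gave slopes from 1.53 to 1.99; the labels say nothing of how the series differed, so no biological explanation was tested.

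NonResponder replicate 14 and Responder replicate 20 had high scores for lymph node stroma. Their B cell scores exceeded the highest other array of the group by 4.10 and 3.75 on the log2 scale, and the B cell gene Ms4a1 stood at 12.3 against a mean of 4.75 and at 12.6 against 5.38. Glycam1, a product of the high endothelial venules of lymph nodes, stood at 11.9 against 4.55 and 12.5 against 4.46, while melanocyte scores were lower than in the other arrays of the group, 8.42 against 9.95 and 7.05 against 9.68. Lymph node tissue in the sampled piece is therefore a candidate explanation, from whole tumour RNA with no sort or gate named in the labels; Ltb of the 5 measured stroma genes is also made by lymphocytes, and Madcam1, an addressin of mucosal nodes, stood at 5.40 against 5.17 in the NonResponder array. Lymphoid tissue that formed inside a tumour would raise the same genes and was not tested.

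More genes were lower than higher in Responder than in NonResponder tumours. Olfactory receptor genes, hardly expressed in tumours, had a median of -0.13 (38 genes, mean level 4.30; 95% bootstrap interval over arrays, 1000 resamples, from -0.18 to -0.07), and 23 of them were called lower and 0 higher by limma. A joint downward shift of dim probe sets by background or normalization could account for part of the pattern, since the median of the genes called lower was itself -0.19. Of the 5414 lower calls, 2007 lie above the dim threshold of 7.01, the median of the gene means, and had a median of -0.29. All genes above the threshold had a median of 0.02 and those under it a median of -0.09. Whether genes between the level of the olfactory receptors and the threshold share the shift was not tested. How many lower calls the shift accounts for is therefore not known. Changes in the share of expressing cells were not tested apart from it.

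Scores and single genes of the PBS and Relapse groups were examined for a sample far from the others. Of 62 such examinations 2 were flagged, which is no more than the 1 in 20 that chance gives. The neutrophil score of PBS replicate 4 was 6.33, against 5.07 to 5.49 in the other 6 PBS tumours. The lymph node stroma score of Relapse replicate 6 was 7.26, against 5.04 to 5.63 in the other 5 Relapse tumours. The Responder minus NonResponder difference of the adipocyte list was smaller in the larger than in the smaller series, by a median of -1.68 (fry adjusted p = 0.0485; 8 of 8 genes lower adjusted over the list alone, camera adjusted p = 0.215 with an estimated correlation). Adipocyte scores were high in NonResponder replicate 14 of the larger series (9.22 against a mean of 6.40 in the others) and in Responder replicate 20 of the smaller one (10.97 against 6.88). Without these 2 arrays, a choice made after the data were seen, the median was -1.21 and the list did not pass (fry adjusted p = 0.199). Probe sets without a listed gene entered no comparison of genes; 3498 of these 9160 changed between Responder and NonResponder, 969 higher and 2529 lower, 27 of them by more than 2-fold.

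Other divisions of the same arrays into groups of the same sizes within title series, 100 each with the real one included, gave the following. As many changed genes as in Responder against NonResponder (8552) came from 1 division, the real one (highest other 2). As many as in Responder against control IgG (6791) also came from 1 (highest other 3103). A share of 1 in 100 is the smallest these draws can give, and it was not adjusted for the number of comparisons. Relapse against NonResponder had the same share (3697; 1 division; highest other 1681), but its count depended on single tumours. Without Relapse replicate 6, 4, 5 or 1 it was 557, 785, 1139 or 1359, and without replicate 2 or 3 it was 4064 or 2793. In the larger series alone, with fewer arrays, it was 0, so chance is not firmly excluded for this comparison. For Stabilization against NonResponder (4074) 3 divisions gave as many, the real one included, and the highest other count was 4363. That share is under 0.05, yet other divisions reached the real count, and 2 genes passed without Stabilization replicate 1. Chance cannot be excluded for Stabilization against Responder (58; 32 divisions; highest other 7305) or for control IgG against PBS (1 gene; 33 divisions; highest other 14). Where limma called 0 genes, all 100 divisions gave as many by definition, so that count says nothing. The highest other count was 4 in NonResponder against control IgG, 5691 in Relapse against Responder and 2 in the interaction. Divisions that call many more genes than the real one, as in Relapse against Responder and in Stabilization against Responder, point to a structure of the samples. Without the doubtful arrays, a choice made after the data were seen, the highest other counts were 281 (real 0) and 847 (real 1), so part of this structure may lie in those arrays. Relapse against NonResponder then gave 7630 genes, and 1 division of 100 gave as many (highest other 4076). Stabilization against NonResponder, with 2 Stabilization tumours left, gave 273 genes, and 11 of 55 divisions gave as many (highest other 2142), so chance cannot be excluded there.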

How the results depend on the processing

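The alternatives without the doubtful arrays, the gene-by-gene array weights and the omission of single doubtful arrays were chosen after the data were seen. Counts of changed genes that moved by more than 1.5 times are given here, and for all of them the cause was not tested, except that leaving out dim genes tests fewer genes and single series hold fewer arrays. No paired analysis was possible because the labels pair no samples, and replicates were numbered here in the order of the arrays.

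Leaving out dim genes gave 4397 genes for Responder against NonResponder (main count 8552), 3448 for Responder against control IgG (6791), 0 for control IgG against PBS (1), 1559 for Relapse against NonResponder (3697; 79.4% higher, against 41.5%), 29 for Stabilization against Responder (58) and 0 for GrowthDelay against Responder (29). Only the larger series gave 550 for Responder against NonResponder, 0 for control IgG against PBS, 0 for Relapse against NonResponder and 1 for GrowthDelay against NonResponder (0). Only the smaller series gave 3467 for Responder against NonResponder, 542 for Relapse against NonResponder, 0 for Stabilization against Responder and 2480 for Stabilization against NonResponder (4074). Without a series block Relapse against NonResponder gave 1621 and Stabilization against Responder 704, and with a 2-level block the latter gave 136. With only the groups compared, control IgG against PBS and Stabilization against Responder gave 0.

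Quantile normalization gave 4132 for Responder against control IgG, 1327 for Relapse against NonResponder (25.1% higher) and 18 for GrowthDelay against Responder. Median centring gave 7349 for Relapse against NonResponder (10.8% higher) and 259 for GrowthDelay against Responder. It moved the median of all genes from -0.06 to -0.18 in the former and from 0.03 to 0.15 in the latter, and from -0.06 to -0.14 in Responder against NonResponder (11185 genes, 18.4% higher, against 36.7%). Array weights gave 11203 for Responder against control IgG, 22 for NonResponder against control IgG, 2273 for control IgG against PBS, 5 for Relapse against Responder, 10409 for Relapse against NonResponder, 12934 for Stabilization against Responder, 14582 for Stabilization against NonResponder, 213 for GrowthDelay against Responder and 8 for the interaction. Their estimate stopped before it converged (weights 0.02 to 133); estimated gene by gene (0.089 to 4.52) the counts were 11192, 21, 132, 5, 10278, 6382, 9942, 156 and 9.

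Without the doubtful arrays Relapse against NonResponder gave 7630, Stabilization against Responder 1 and Stabilization against NonResponder 273. Without them the larger series alone gave 4396 for Responder against NonResponder, 0 for control IgG against PBS, 2 for Relapse against NonResponder, 51 for GrowthDelay against Responder and 2 for GrowthDelay against NonResponder, and the smaller series alone 1849 for Responder against NonResponder, 0 for Stabilization against Responder and 364 for Stabilization against NonResponder. Leaving out 1 array at a time gave 0 to 2 for control IgG against PBS (PBS replicates 1, 2, 3 and 5 only), 0 for Relapse against Responder, 557 to 5626 for Relapse against NonResponder, 1 to 2727 for Stabilization against Responder, 2 to 6666 for Stabilization against NonResponder, 0 to 116 for GrowthDelay against Responder and 0 to 28 for GrowthDelay against NonResponder. With 1 GrowthDelay array left, the lone sample is assumed to vary like the other groups.

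Named genes called in the main fit or in the alternative changed sign in 5 cases. Cpa3 in Responder against NonResponder turned to -0.077 in the larger series alone. In Stabilization against Responder Ereg turned to -0.051, Pdcd1 to 1.85 and Cd209a to -0.20 with array weights, and Pdcd1 to 1.47 with gene-by-gene weights. Sign changes of genes called in neither setting were not counted. The next counts are of results, each a named gene in a comparison, 1155 in all. Of these 165 lost and 4 gained the call in the larger series alone (920 results), 87 lost and 44 gained it without the doubtful arrays, 55 and 7 with quantile normalization, 50 and 34 without the block, 5 and 208 with array weights, 7 and 150 with gene-by-gene weights and 3 and 2 without dim genes, a setting that keeps only 682 results.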

Other observations

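The comparison of Stabilization with NonResponder tumours held further groups. Endothelial genes rose in 7 of 12 members (9 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation), with the junction protein Cdh5 at 1.72 ± 0.45 and Emcn at 1.13. Complement and coagulation genes rose in 6 of 10 (8 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), with the plasminogen activators Plau at 0.98 and Plat at 1.29, and dedifferentiation genes in 6 of 14 (10 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), with Wnt5a at 1.10. Cytotoxic genes rose in 6 of 16 (10 adjusted over the list alone, adjusted p = 0.311 with an estimated correlation), class II genes in 6 of 9 (6 adjusted over the list alone, adjusted p = 0.311 with an estimated correlation) and hypoxia genes in 4 of 14 (4 adjusted over the list alone, adjusted p = 0.311 with an estimated correlation), with Tbx21 at 1.86, H2-Ab1 at 1.72 and Vegfa at 0.81. Without the doubtful arrays, chosen after the data were seen, 1 cytotoxic gene and 0 genes of the other lists named here changed in limma.

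Relapse tumours also differed from NonResponder tumours in single genes of other lists. The antibody chain gene Ighm rose by 2.02 ± 0.62 (adjusted p = 0.0238), by 0.81 within the larger and 3.41 within the smaller series, where the B cell list had medians of -0.25 and 0.63. The smaller series holds Relapse replicate 6, whose lymph node stroma score was 7.26, against 5.04 to 5.63 in the other Relapse tumours. Further rises were the mast cell protease Cpa3 (0.78 ± 0.26), the vessel receptor Eng (0.51 ± 0.16) and Tgfb1 (0.85 ± 0.31), while Ankrd37, a target of the hypoxia response, fell by 0.72 (SE 0.27).

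A lower share of melanoma cells would lower all melanocytic genes alike if the array followed them equally. The mean of Pmel, Mlana, Tyr, Tyrp1 and Dct minus Sox10, taken within each array, was lower in Responder than in NonResponder tumours. The difference was -0.40 ± 0.14 (SE, 27 against 23 arrays), and -0.42 ± 0.14 without the doubtful arrays. It was -0.51 within the larger and -0.23 within the smaller series, and a permutation test of the plain mean of these gave p = 0.00593 (two-sided). Whether the array followed these genes equally was not tested, so a lower share of melanoma cells is not excluded. In the smaller series both the 5 genes and Sox10 were lower. The mean of the 5 genes itself differed by -0.40 ± 0.21 (-0.15 within the larger and -0.80 within the smaller series) and Sox10 by 0.003 ± 0.25, which averages 0.36 in the larger and -0.57 in the smaller series. In the larger series the difference thus came mostly from higher Sox10, so whether pigment gene expression per melanoma cell was lower stays open. Of the 5, only Pmel was among the list members called lower and named above.

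Relapse tumours might lie on the Responder side of the axis from NonResponder to Responder tumours. The axis (200 genes) was taken from one series and scored in the other. Relapse exceeded NonResponder tumours by 0.47 (permutation p = 0.0714, adjusted p = 0.107; 0.68 in the larger and 0.26 in the smaller series; above the NonResponder mean in 6 of 6 tumours), Responder exceeded NonResponder tumours by 0.44 (permutation p = 0.00296, adjusted p = 0.00888), and Relapse differed from Responder tumours by 0.04 (permutation p = 0.884, adjusted p = 0.884). The test pooled series of unequal spread, with an SD of NonResponder tumours of 0.81 in the larger series, where NonResponder replicate 14 stood at 2.42, and of 0.091 in the smaller one. In the smaller series all 3 Relapse tumours (0.222 to 0.291) lay above every NonResponder tumour (highest 0.107). The pooled test missed its threshold and was not repeated without the doubtful arrays, so the position of the Relapse tumours stays open.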
